A study of Mus musculus with 18 samples.

How the data were processed

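RNA was measured by bulk sequencing in microglia and astrocytes that had been sorted by flow cytometry from the whole brains of 9 mice, which gave 18 libraries. The strain was C57BL/6j, and the genotypes were WT and APP-NLGF, a knock-in of a humanised and mutated amyloid precursor into the mouse App gene. Library names carry a mouse number that the microglia and astrocyte libraries share, so each mouse gave 1 library of each cell type. All 18 library names carry C3WT, so C3-deficient mice were not analysed here. Each cell type had 4 WT mice, of which replicate 1 was female and the other 3 male, and 5 APP mice, of which replicate 1 was male and the other 4 female.

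Per the submitters' processing notes, the steps used FastQC 0.11.8, Trimmomatic 0.39, STAR 2.7.3a, SAMtools 1.9, edgeR 3.32.1 and limma 3.46.0 with the mouse build mm10. The counting tool, the annotation and the use of strand are not given in the sources used here. The deposited raw tables, 1 per cell type, hold whole read counts of 24421 gene symbols per library. The names of the deposited tables say that outliers had been left out, and which samples these were is not given in the sources used here. The deposited normalized tables hold log2 values of 12902 genes in microglia and 14141 in astrocytes. These values equal log2 of the count plus 0.5 over a normalized library size plus 1, on the scale of CPM, up to 1 constant per library (tolerance 1e-09). Gene positions come from a RefSeq annotation of GRCm38.p6, in which 23204 of the 24421 symbols were found.

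All comparisons started from the raw counts. Each cell type was fitted on its own with edgeR 4.0.16 in R 4.3.3, as APP against WT with sex as a covariate. Genes were kept by filterByExpr by genotype (minimum count 10, minimum total 15) and libraries were scaled by TMM. The quasi-likelihood F-test was used with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with standard errors (SE), and levels as CPM, counts scaled to a common TMM-adjusted library total, as mean ± SD. The difference between the responses of the cell types was tested as an interaction over all 18 libraries, with cell type by sex as covariates, and is given as microglia minus astrocytes. The overlap of the calls was tested with Fisher's exact test. In this interaction the pair of libraries of a mouse was not modelled. Profiles relative to their group, of libraries from the same mouse, correlated at Pearson r of 0.0678 to 0.401, and 8 of 9 microglia libraries matched their own mouse's astrocyte library best. With the mouse as a replicate block, 2948 genes differed against 3357 without it.

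Before the data were examined, 34 lists with 589 genes were fixed from general knowledge, covering microglial and astrocytic states, immune pathways, metabolism and markers of other cell types. They were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives over all libraries. Fry asks whether the genes of a list changed, without comparing them with the genes outside it. List tests with libraries left out or with a changed model used the preset correlation only. They were run within each cell type and not for the interaction. The list of 13 mitochondrially encoded genes had 0 members in the tables and was not tested. Members of a list were also adjusted over the list alone. The lists share genes: the microglial marker, homeostatic and disease-associated lists overlap with those for lysosome, complement and lipid handling, and both cell types express many of them.

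The genes named in the text follow a rule written before the data were examined. It takes C3 and App in every group, and the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM whose APP libraries all lay on one side of all WT libraries. It adds up to 4 called members of each list by adjusted p, or the first 2 by p where no member was called. For the interaction it takes 6 genes in each direction. It left out predicted, clone-named and sex-linked genes. The text gives a part of the list members and states where a gene was chosen after its values were seen.

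The alternatives fixed beforehand were DESeq2 1.42.0 size factors and its Wald test, no filter, a filter of 50 counts in 4 libraries, limma voom with and without sample quality weights, and robust dispersion. Others were no sex covariate, each sex alone, each library left out in turn, the replicate number as a block, the deposited log2 values, and a 2-fold threshold. Alternatives chosen after seeing the data were leaving out WT replicates 1 and 4 together, the mean level of the endothelial markers as a further covariate for astrocytes, a filter by cell type and genotype for the interaction, and leaving out each mouse for the overlap of calls.

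The microglial share of each astrocyte library was estimated after seeing the data, as the median over microglia-specific genes of the astrocyte library's CPM over the CPM of the same mouse's microglia library. These genes had at least 100 CPM in microglia and at most 3% of that in astrocytes. A share was also tested on genes kept aside from its estimate, which had passed the same filter.

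On simulated counts with 200 changed genes, the fits found 71% of 2-fold and 92% of 4-fold changes among 12976 genes for microglia. They found 60% and 91% among 14822 genes for astrocytes, and 36% and 76% among 14636 genes for the interaction. Total counts ranged from 8834866 to 22522407 per library. Counting intervals are 95% exact intervals, and folds against a group without counts use a floor of 3 counts over the group. Both cover counting error only, since reads carry no molecular identifiers. Reads of near-identical paralogs, of overlapping genes and of antisense partners cannot be told apart where the counting did not use strand, so such genes are uncertain.

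The labels give no sequencing batch, day or age. Sequence variants, splicing and single cells were not analysed here, and some single genes are not reported here.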

Results

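RNA was counted per gene in 18 libraries, 9 of sorted microglia and 9 of sorted astrocytes, from 4 WT and 5 APP mice. Total counts ranged from 8834866 to 11700620 in WT microglia, from 11858295 to 18363154 in APP microglia, from 10569776 to 21865752 in WT astrocytes and from 18125387 to 22522407 in APP astrocytes. Genes with at least 1 count numbered 15379 to 16287, 16146 to 16469, 16200 to 17208 and 17188 to 17463 in the same order. The ribosomal RNA gene Rn45s took between 2.60% and 12.5% of the counts of a library, in microglia 5.74% to 9.76% in WT and 3.20% to 6.46% in APP. The nuclear RNA Malat1 took 2.71% to 2.96% in WT microglia and 1.36% to 1.97% in APP microglia. Sex-linked genes gave 0 mismatches with the sex labels, and 8 genes were called between males and females in microglia and 7 in astrocytes (edgeR), all of them sex-linked.

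C3, whose deficiency the series title names, and App, the gene carrying the knock-in, were read first. All 18 library names carry C3WT. In microglia C3 rose from 3.55 ± 0.750 CPM (SD, n = 4) to 22.8 ± 4.90 CPM (n = 5), a log2 fold change of 2.89 (SE 0.20, adjusted p = 9.51e-07, edgeR), with 2.81 in females and 2.95 in males. C3 lies on chromosome 17 from 57203967 to 57228136 (GRCm38.p6). In astrocytes C3 lay at 19.9 ± 12.1 CPM in WT and 53.6 ± 19.7 CPM in APP, above every WT library in all 5 APP libraries. The astrocyte difference of 2.21 (SE 0.74) did not pass (adjusted p = 0.0566), and it was 3.94 in females (adjusted p = 0.00228) and 0.72 in males (adjusted p = 0.494), each sex with a lone library of 1 genotype. It was 0.71 without WT replicate 1, the female (adjusted p = 0.393). Without APP replicate 1, the male, it was 3.96 (adjusted p = 0.00881), and without WT replicate 3 it was 2.39 (adjusted p = 0.0443). With sex as a covariate, leaving out WT replicate 1 leaves the genotype contrast to the males, and leaving out APP replicate 1 leaves it to the females. Those values repeat the contrasts by sex and are no separate checks, here and for the genes below. The share of microglial RNA gave 0.0068 of the astrocyte difference.

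App RNA rose modestly in microglia, from 282 ± 15.2 to 386 ± 38.4 CPM, a log2 fold change of 0.43 (SE 0.10, adjusted p = 0.00618, edgeR). It lies on chromosome 16 from 84952666 to 85175255. The rise was 0.61 in females (adjusted p = 0.0103) and 0.25 in males (adjusted p = 0.141), and without WT replicate 1 it was 0.23 (adjusted p = 0.219). In astrocytes App lay at 409 ± 227 CPM in WT and 710 ± 156 CPM in APP, and the difference of 1.11 (SE 0.46) did not pass (adjusted p = 0.102). It was 1.68 in females (adjusted p = 0.00716), 0.51 in males (adjusted p = 0.762) and 0.50 without WT replicate 1 (adjusted p = 0.634). With the endothelial marker level as a covariate, chosen after seeing the data, it was 0.05 (adjusted p = 0.895).

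**Figure D1:**
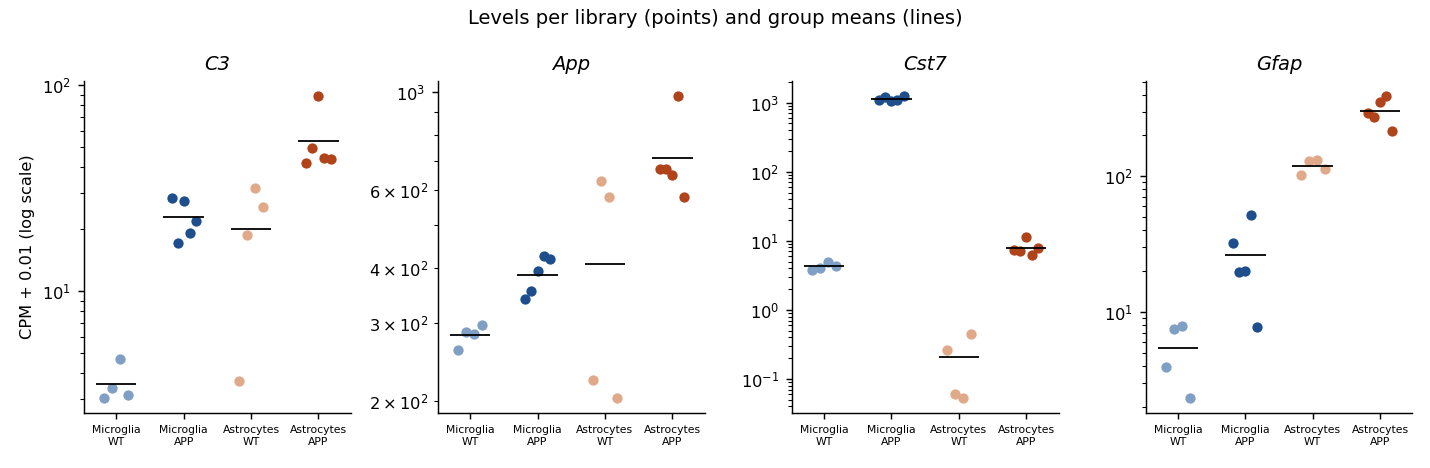
Levels of C3, App, Cst7 and Gfap in CPM plus 0.01 on a log axis, for each of the 18 libraries by cell type and genotype, with a line at each mean. C3 of the 5 APP libraries lies above that of the 4 WT libraries in both cell types.

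The comparison of microglia asks how these cells respond to amyloid in the knock-in mice. They took on the disease-associated state, a program of phagocytic and lipid-handling genes known from cells around plaques: all 40 measured genes of that list rose. The homeostatic genes, which mark resting microglia, fell in 24 of 30 cases. Interferon, antigen presentation, lysosome, cytokine and glycolysis genes rose with the disease-associated ones, and markers of macrophages of the brain borders fell. With an estimated correlation between genes, only the disease-associated and lipid handling lists were called. With fry, which does not compare a list with other genes, all 17 lists called by camera passed.

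Of 13116 genes tested, 5022 changed (edgeR), 2509 up and 2513 down, and 997 rose and 426 fell by at least 2-fold. In 2598 genes all 5 APP libraries lay above all 4 WT libraries and in 2522 below, where chance gives 0.794% of genes in each direction. Without WT replicate 1, the only WT female, 2641 genes were called, and 59.83% of these rose against 49.96% with it. Females alone gave 4223 genes and males alone 2112, with a lone WT female and a lone APP male that are assumed to vary like the others. WT 1 and 4 lay apart from WT 2 and 3 on the second principal component (37.5 and 16.4 against −40.1 and −28.9), with 28.5 and 31.1 CPM of mural markers against 189 and 159 CPM.

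The disease-associated list had a median log2 fold change of 2.35 (camera, adjusted p = 2.55e-139, 0.0109 with an estimated correlation). All 40 genes passed adjusted over the list alone, and all 40 remained called without WT replicate 1. Cst7, which encodes the protease inhibitor cystatin F, rose from 4.24 ± 0.464 to 1132 ± 80.9 CPM, a log2 fold change of 8.05 (SE 0.12, adjusted p = 6.58e-12). Clec7a, the receptor dectin-1, rose by 4.49 (SE 0.11, adjusted p = 3.07e-10), and the growth factor gene Igf1 by 4.59 with the same adjusted p. Itgax, the integrin CD11c, rose by 5.78 and Spp1, osteopontin, by 6.75. The largest rise was that of Gpnmb, a lysosomal membrane glycoprotein on chromosome 6 from 49036518 to 49058182, from 0.775 ± 0.665 to 733 ± 140 CPM (9.71, SE 0.34, adjusted p = 5.21e-09). Others among the 10 largest rises were Dkk2, a Wnt antagonist (8.88), Mamdc2, a matrix protein (8.88), Baiap2l2, which shapes membranes (8.72), Atp6v0d2, a subunit of the proton pump of lysosomes (8.22), and Lgi2, a secreted synaptic protein (7.48). The ion channel gene Trpm1 went from 3 counts over the WT group to 2008 over the APP group (ratio 391, 95% counting interval 134 to 1900), and Asb11, of the ubiquitin system, from 2 to 433 (ratio 127, interval 34.8 to 1050).

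The homeostatic list fell with a median of −0.63 (adjusted p = 8.75e-13, but 0.235 with an estimated correlation), and 25 fell adjusted over the list alone. Of the 24 genes, 18 remained called without WT replicate 1. Tmem119, a membrane protein used to mark microglia, fell from 2758 ± 343 to 911 ± 153 CPM (−1.47, adjusted p = 7.91e-06). P2ry12, the ADP receptor that guides processes, changed by −1.12, Sall1, which holds microglial identity, by −0.76, the crystallin gene Crybb1 by −1.93 and Ecscr, a cell surface regulator, by −2.11. The largest fall was that of Ptger3, a prostaglandin E2 receptor (−3.23, adjusted p = 6.61e-05), followed by the transcription factor Mycl (−3.09), the adaptor Bank1 (−2.87), the metalloproteinase Mmp28 (−2.64) and Ccdc162 (−2.58). Pecam1 (−2.56), Klk10 (−2.55), Nhs (−2.52), Slc5a10 (−2.51) and Gpr165 (−2.48) completed the 10 largest falls. Klk10 had an adjusted p of 0.0849 without WT replicate 1. The 10 microglial markers fell as a list with a median of −0.44 (adjusted p = 0.00704, 0.426 with an estimated correlation), 6 down and 1 up, with the same counts adjusted over the list alone, of which 3 of 7 remained called without WT replicate 1.

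Immune pathways rose together. Of 33 interferon response genes 27 rose, also 27 adjusted over the list alone (median 1.05, adjusted p = 1.51e-08, 0.397 with an estimated correlation), with the antiviral sensor Oasl2 up by 2.08 and the DNA sensor family member Ifi204 by 1.86. MHC class I presentation rose in 14 of 16 genes, 15 adjusted over the list alone (median 0.78, adjusted p = 8.93e-10, 0.172 with an estimated correlation), led by H2-D1 from 177 to 669 CPM (2.04) and H2-K1 (1.50). These class I genes are near-identical copies, so their reads are uncertain. MHC class II presentation had 8 genes up and 1 down of 13, 9 and 1 adjusted over the list alone (median 0.59, adjusted p = 0.00502, 0.445 with an estimated correlation and 0.0874 without the sex covariate), and the invariant chain Cd74 rose by 1.75. Complement had 11 up and 2 down of 23, 12 and 3 adjusted over the list alone (median 0.41, adjusted p = 0.00171, 0.164 with an estimated correlation). Cytokine and NF-kB genes had 20 up and 2 down of 27, 21 and 4 adjusted over the list alone (median 1.31, adjusted p = 1.44e-08, 0.172 with an estimated correlation). The chemokine Ccl3 rose by 2.57, Cxcl16 by 1.20 and Tnf by 2.00. The calls that remained without WT replicate 1 were 25 of 27 for interferon, 11 of 14 for class I, 8 of 9 for class II, 8 of 13 for complement and 18 of 22 for cytokines.

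Lysosome and metabolic genes moved the same way. Lysosome genes had 26 up and 1 down of 34, 27 and 3 adjusted over the list alone (median 0.77, adjusted p = 2.68e-20, 0.172 with an estimated correlation), among them the tetraspanin Cd63 (1.88) and the protease Ctsl (1.92). Lipid handling had 15 up and 4 down of 26, 15 and 5 adjusted over the list alone (median 1.01, adjusted p = 8.52e-15, 0.0393 with an estimated correlation). Lpl, lipoprotein lipase, rose from 20.5 to 957 CPM (5.53), Ch25h, which makes 25-hydroxycholesterol, by 4.91, the fatty acid carrier Fabp5 by 5.35 and Apoe from 685 to 7129 CPM (3.42). Cholesterol biosynthesis rose in 14 of 24 genes, 15 adjusted over the list alone (median 0.61, adjusted p = 0.000143, 0.29 with an estimated correlation), with the sterol sensor partner Insig1 up by 1.16. Glycolysis rose in 14 of 19 genes, also 14 adjusted over the list alone (median 1.33, adjusted p = 1.95e-12, 0.172 with an estimated correlation), with Hif1a up by 2.52 and the enzyme Tpi1 by 1.86. With WT replicate 1 left out, 21 of 27 lysosome, 16 of 19 lipid, 7 of 14 cholesterol and 14 of 14 glycolysis calls remained, and the cholesterol median was 0.40 (0.35 without WT 1 and 4).

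Cell cycle genes rose in 21 of 30 cases, 23 adjusted over the list alone (median 1.22, adjusted p = 0.00029, 0.29 with an estimated correlation), with the kinase Cdk1 up by 2.32 and the proliferation marker Mki67 by 1.46. Immediate early genes, which also respond to tissue dissociation, had 14 up and 1 down of 28, 15 and 1 adjusted over the list alone (median 0.40, adjusted p = 0.000949, 0.29 with an estimated correlation), with the transcription factor Egr2 up by 2.06. Of these, 13 of 21 cell cycle and 9 of 15 immediate early calls remained without WT replicate 1, with medians of 1.41 and 0.26. Border-associated macrophage markers fell in 8 of 12 cases, 9 adjusted over the list alone (median −1.32, adjusted p = 4.72e-05, 0.275 with an estimated correlation). Their sum went from 1792 ± 61.3 to 530 ± 118 CPM, and 5 of 8 calls remained without WT replicate 1. Stab1, a scavenger receptor, went from 1330 to 373 CPM (−1.81), and the mannose receptor Mrc1 changed by −1.76 and the haemoglobin scavenger Cd163 by −1.51.

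Lists written for other cells were read in microglia too. The A1-labelled astrocyte list, which holds C3 and class I genes, had 7 up and 1 down of 13, the same adjusted over the list alone (median 0.95, adjusted p = 0.00814, 0.215 with an estimated correlation, 0.0736 without APP replicate 1 and 0.0875 without the sex covariate). The disease-associated astrocyte list had 12 up and 1 down of 26, 13 and 1 adjusted over the list alone (median 0.85, adjusted p = 3.11e-05, 0.172 with an estimated correlation), and shares Apoe, Ctsb and Cd63 with microglia. Its median was 0.49 without WT replicate 1, where 8 of 13 calls remained, and 0.27 without WT 1 and 4. Pan-reactive (adjusted p = 0.0777), A2-labelled (0.402), homeostatic astrocyte (0.729, median 0.09 against a test pointing down), synaptogenic (0.934, median 0.05 against a test pointing down) and amyloid processing (0.0777) lists did not pass. Among amyloid processing genes Aplp2, an App paralog, rose by 2.44, the adaptor Apbb2 by 1.64, and Ide, the insulin-degrading enzyme, changed by −0.66. Markers of astrocytes (adjusted p = 0.967), neurons (0.967), oligodendrocytes (0.0864), their precursors (0.409), endothelium (0.732), mural cells (0.127), monocytes and neutrophils (0.236), lymphocytes (0.236), ependyma and choroid plexus (0.0864), erythroid cells (0.967) and the sex-linked list (0.754) did not pass either. Gfap in these libraries rose by 2.54 (adjusted p = 0.00563), by 2.46 without WT replicate 1 (adjusted p = 0.0504) and by 2.66 without APP replicate 1 (0.0767). Ttr rose by 2.41, but by 0.90 without WT replicate 1 (adjusted p = 0.145), while Cspg4 (4.09) and Flt1 (4.39) remained called without it.

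**Figure D2:**
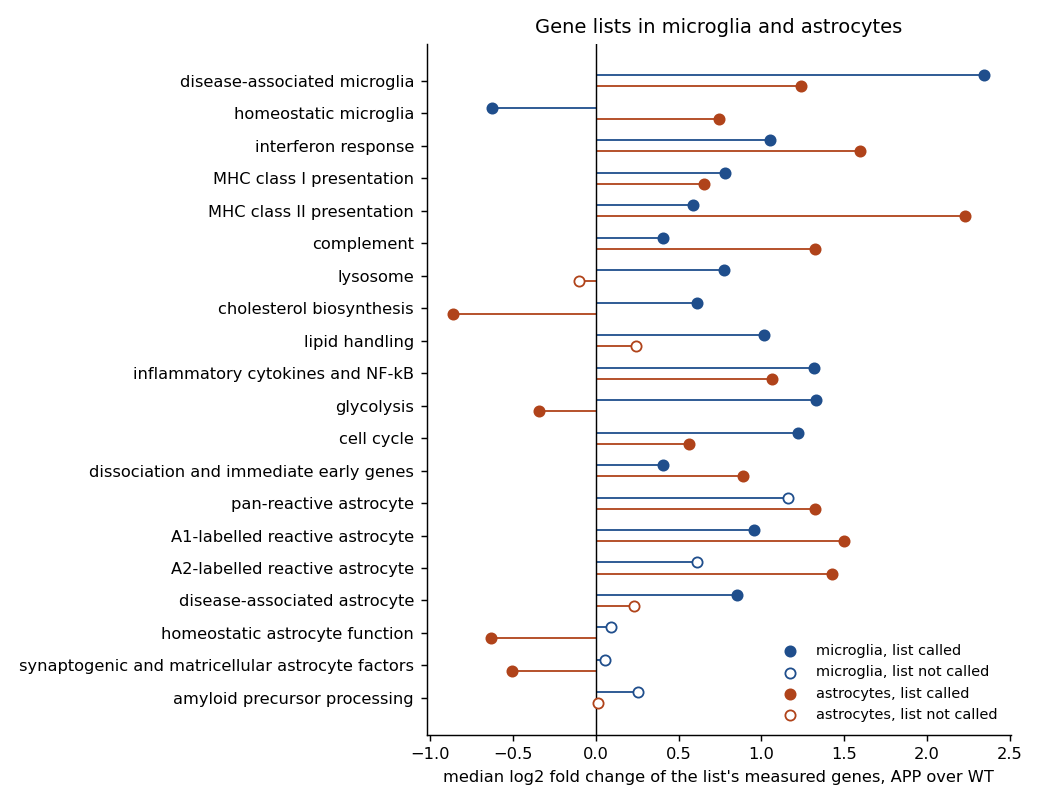
Median log2 fold change, APP against WT, of each gene list in microglia and astrocytes, with filled points for lists that passed the camera test. The disease-associated microglia list rose in both cell types, and cholesterol biosynthesis rose in microglia (0.61) and fell in astrocytes (−0.86). In astrocytes the microglial share gave a median of 1.18 of the rises of the disease-associated microglia list. The disease-associated astrocyte list did not pass there (camera, adjusted p = 0.119). With an estimated correlation the disease-associated microglia list was called in microglia alone (0.0571 in astrocytes) and cholesterol in neither (0.29 and 0.0885).

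The comparison of astrocytes asks the same of the other glial type. Interferon, antigen presentation and reactive astrocyte genes rose, while cholesterol biosynthesis and genes of the homeostatic functions of astrocytes fell. The largest rises were transcripts typical of microglia, whose share in the APP astrocyte libraries was higher than in the WT ones. Single calls rested mostly on WT replicate 1, without which few genes passed. Most lists still passed without it, but this was tested at the preset correlation of 0.01 only. The estimated correlation was 0.586 for interferon and 0.706 for homeostatic astrocyte genes, so those passes do not show that the lists hold across mice. Over all libraries, 4 of the lists were called with an estimated correlation: homeostatic microglia, complement, A2-labelled and microglial markers. The interferon, antigen presentation, pan-reactive, A1-labelled, cholesterol and homeostatic astrocyte lists were not. With fry over all libraries these lists passed (adjusted p from 0.000702 to 0.00925). Fry does not set them apart from the many other genes that changed, and it was not run without WT replicate 1.

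Of 14957 genes tested, 3836 changed (edgeR), 1812 up and 2024 down, and 1028 rose and 202 fell by at least 2-fold. All 5 APP libraries lay above all 4 WT libraries in 1482 genes and below in 1718, where chance gives 0.794% of genes in each direction. Without WT replicate 1, the only WT female, where 3 WT males are compared with the lone APP male, 34 genes were called, 28 up and 6 down, and 2713 of all genes had an unadjusted p under 0.05. Leaving out any other library gave 2749 to 4217 genes. Females alone gave 4916 genes. Males alone gave 0 with edgeR, where 1575 genes had an unadjusted p under 0.05, and no other tool was run on the males or without WT replicate 1. All 3836 genes kept their direction without WT replicate 1. The design may bring this about in part, since the male contrast left then is a part of the full one. This was not tested. WT replicates 1 and 4 lay apart from the others on the first principal component (−89.4 and −69.7, against −6.09 and −0.342 for WT 2 and 3 and 23.7 to 39.1 for APP). They held 613 and 541 CPM of endothelial markers, against 3934 and 3072 in WT 2 and 3 and 3806 ± 654 in APP. Without both, chosen after seeing the data, 142 genes were called, and with the endothelial level as a covariate 382.

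**Figure D3:**
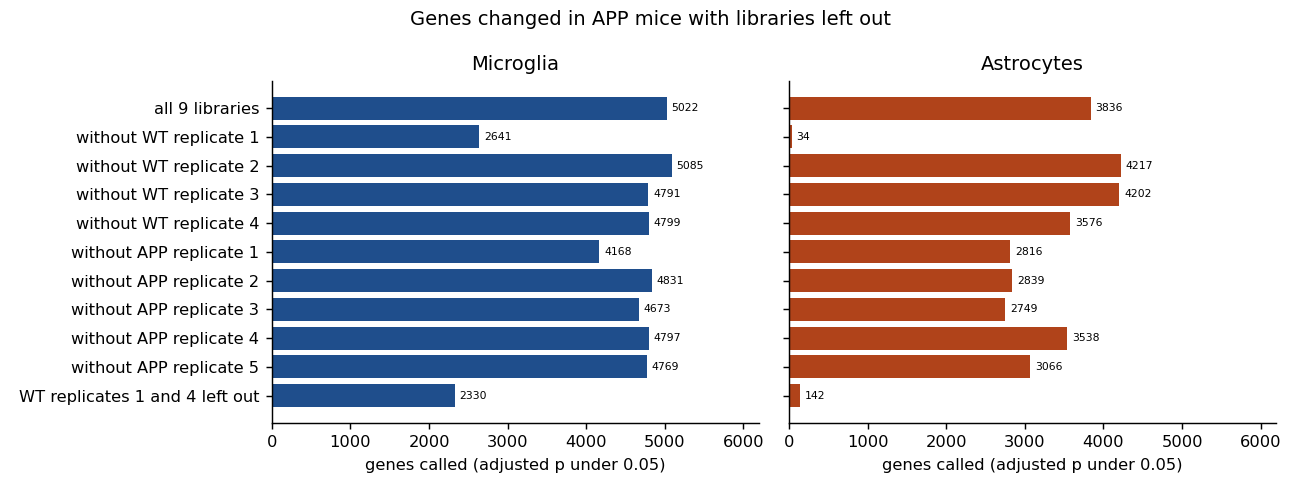
Number of genes called between APP and WT with each library left out in turn, for microglia and astrocytes. Without WT replicate 1 the number was 2641 in microglia and 34 in astrocytes.

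Transcripts typical of microglia made up the largest rises. The share of microglial RNA in astrocyte libraries was 0.286% ± 0.102 in WT and 0.998% ± 0.134 in APP (SD, n = 4 and 5; exact permutation test, two-sided, p = 0.00794, over 126 splits, the smallest they can give). Itgax went from 1 count over the WT group to 1080 over the APP group (ratio 701, 95% counting interval 126 to 27700) and Clec7a from 1 to 779 (ratio 506, interval 90.5 to 20000). Cst7 rose by 5.48, the chemokines Ccl3 by 5.15 and Ccl6 by 4.86, the receptor Trem2 by 4.04 with its adaptor Tyrobp (4.35), the RNA sensor Tlr7 by 4.01 and the tetraspanin Cd37 by 4.39. Ccl4 went from 2 counts to 206 (ratio 66.9, interval 18.3 to 556). Leaving out WT replicate 1, Cd37 rose by 3.90 (adjusted p = 0.0794) and Ccl4 had an adjusted p of 0.104, and the other 8 of these 10 remained called. C1qa, which starts the classical complement pathway, rose from 3.459 ± 0.460 to 31.3 ± 2.80 CPM (adjusted p = 6.23e-06), and by 3.24 without WT replicate 1 (adjusted p = 0.00026).

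**Figure D4:**
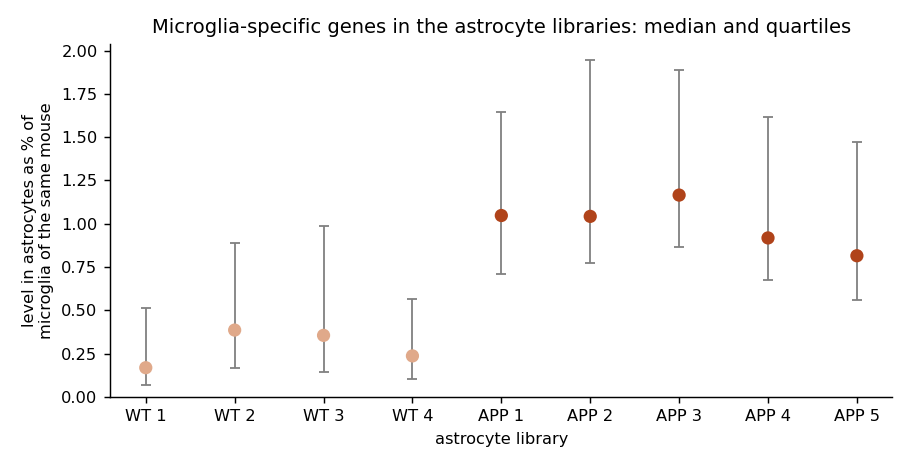
Level of microglia-specific genes in each astrocyte library as a percentage of that in the same mouse's microglia library, as median and quartiles over 183 genes. The medians were 0.168% to 0.385% in the 4 WT and 0.815% to 1.17% in the 5 APP libraries.

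The lists with microglial genes rose in astrocytes as well. The disease-associated microglia list had 20 up and 3 down of 38, 22 and 3 adjusted over the list alone (median 1.24, adjusted p = 9.25e-14, 0.0571 with an estimated correlation). Homeostatic microglia had 17 up and 3 down of 30, 20 and 3 adjusted over the list alone (0.75, adjusted p = 1.54e-08, 0.048 with an estimated correlation), and microglial markers 8 up and 1 down of 10, 9 and 1 adjusted over the list alone (2.20, adjusted p = 3.09e-14, 0.048 with an estimated correlation). MHC class II rose in 6 of 11 genes, 7 adjusted over the list alone (2.23, adjusted p = 1.4e-07, 0.0885 with an estimated correlation), and cytokines had 10 up and 1 down of 18, 11 and 1 adjusted over the list alone (1.07, adjusted p = 8.98e-06, 0.0749 with an estimated correlation). Genes of these lists can be among those that set the microglial share, so medians of it near 1 are in part built in. The microglial share, times the level in the same mouse's microglia, gave a median of 1.18 of the rise for the disease-associated genes that rose. It gave 0.855 for the homeostatic ones, 1.2 for the markers, 1.03 for class II and 1.15 for cytokines. Complement had 17 up and 2 down of 27, 19 and 2 adjusted over the list alone (1.32, adjusted p = 9.25e-14, 0.048 with an estimated correlation), with a median of 0.117. C4b, a complement gene that astrocytes express, rose from 216 ± 20.7 to 437 ± 52.9 CPM (1.06, adjusted p = 0.00263, 0.086 without WT replicate 1), and the microglial share gave 0.00232 of that rise. Calls that remained without WT replicate 1 were 8 of 23, 3 of 20, 4 of 9, 4 of 6, 1 of 11 and 5 of 19 for these lists in the order given, and their medians were 0.93, 0.52, 1.66, 1.65, 0.56 and 0.99.

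Interferon response genes rose in 26 of 32 cases, 29 adjusted over the list alone (median 1.60, adjusted p = 4.98e-14, 0.222 with an estimated correlation). The microglial share gave a median of 0.0159 of these rises. The antiviral genes Ifit2 and Ifit3 rose by 0.88 and 1.29. MHC class I rose in 12 of 16 genes, 13 adjusted over the list alone (0.65, adjusted p = 2.59e-07, 0.182 with an estimated correlation), with its activator Nlrc5 up by 2.22 and H2-K1 by 0.58, and a median share of 0.0822. Leaving WT replicate 1 out, 0 of the 26 interferon and 0 of the 12 class I calls remained (edgeR), with log2 fold changes of 0.86 for Ifit2 (adjusted p = 0.141), 1.59 for Ifit3 (0.0995), 1.93 for Nlrc5 (0.103) and 0.54 for H2-K1 (0.124). At an unadjusted p under 0.05, 22 of 33 interferon and 11 of 16 class I genes passed without it. Ifit3 was also lost without APP replicate 1 (adjusted p = 0.0775). The interferon list itself still passed without WT replicate 1 at the preset correlation (median 1.22, camera, adjusted p = 8.21e-18).

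Cholesterol biosynthesis, which astrocytes carry out for neurons, fell in 21 of 24 genes, 22 adjusted over the list alone (median −0.86, adjusted p = 2.29e-19, 0.0885 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, fell from 405 ± 28.1 to 233 ± 20.6 CPM (−0.85, adjusted p = 0.00218), Idi1 from 17.4 ± 1.61 to 8.57 ± 0.424 CPM (−1.05, adjusted p = 0.002), and Mvd and Nsdhl changed by −1.49 and −0.85. Without WT replicate 1, 0 of the 21 genes were called (edgeR), while 20 of 24 had an unadjusted p under 0.05. Hmgcs1 then changed by −0.86 (adjusted p = 0.102), Idi1 by −1.07 (0.0944) and Mvd by −1.39 (0.121). The list then passed at the preset correlation with a median of −0.81 (camera, adjusted p = 1.73e-16). Glycolysis had 1 up and 8 down of 19, 1 and 10 adjusted over the list alone (−0.34, adjusted p = 0.00395, 0.327 with an estimated correlation), with the astrocytic aldolase Aldoc from 3666 ± 703 to 2020 ± 211 CPM (−1.01, adjusted p = 0.00522; −0.98 and 0.16 without WT replicate 1). With that library left out 0 of the 9 glycolysis calls remained (edgeR), and 7 of 19 genes had an unadjusted p under 0.05. Lysosome (adjusted p = 0.782) and lipid handling (0.234) did not pass as lists.

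Reactive astrocyte genes rose. Gfap, the filament protein that marks reactive astrocytes, rose from 120 ± 13.8 to 305 ± 69.2 CPM (1.41, SE 0.21, adjusted p = 0.00522), with 1.57 in females, 1.21 in males (adjusted p = 0.358) and 1.20 without WT replicate 1 (adjusted p = 0.134). Pan-reactive genes rose in 6 of 11 cases, 9 adjusted over the list alone (median 1.32, adjusted p = 1.14e-05, 0.171 with an estimated correlation), among them the adhesion receptor Cd44 (0.97) and the protease inhibitor Serpina3n (1.34). The A1-labelled list rose in 7 of 13 genes, 9 adjusted over the list alone (1.50, adjusted p = 1.57e-05, 0.234 with an estimated correlation), with the interferon-induced GTPases Iigp1 (2.37) and Gbp2 (1.80). The A2-labelled list rose in 8 of 11 genes, 10 adjusted over the list alone (1.43, adjusted p = 0.000125, 0.048 with an estimated correlation), with the surface protein Cd109 (1.96) and Cd14 (2.44). The medians of the 3 lists were 0.69, 1.02 and 1.07 without WT replicate 1 and 0.40, 0.77 and 0.97 without WT 1 and 4. The microglial share gave medians of 0.00187, 0.0882 and 0.0272 of the rises of the 3 lists. Of these calls 0 of the 6, 0 of the 7 and 0 of the 8 remained without WT replicate 1 (edgeR), with log2 fold changes of 1.03 for Cd44 (adjusted p = 0.15), 1.77 for Serpina3n (0.122), 2.10 for Iigp1 (0.14), 1.42 for Gbp2 (0.174), 1.10 for Cd109 (0.147) and 2.18 for Cd14 (0.104). At an unadjusted p under 0.05, 6 of 11, 7 of 13 and 7 of 12 genes passed without it. Without APP replicate 1, Cd44 (0.065) and Serpina3n (0.149) were lost as well. The disease-associated astrocyte list did not pass (adjusted p = 0.119), with 10 up and 5 down of 26, of which 0 of 15 remained called without WT replicate 1 (edgeR, 13 of 26 at an unadjusted p under 0.05).

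Homeostatic astrocyte genes fell in 19 of 28 cases, 22 adjusted over the list alone (median −0.63, adjusted p = 2.19e-12, 0.243 with an estimated correlation). Aldh1l1, the folate enzyme used as an astrocyte marker, fell from 451 ± 90.2 to 251 ± 20.2 CPM (adjusted p = 0.00315), the glutamate transporter Slc1a3 changed by −0.82 and the receptor subunit Grin2c by −1.18. Astrocyte markers had 7 down and 1 up of 10, the same adjusted over the list alone (−0.63, adjusted p = 0.000164, 0.246 with an estimated correlation), and their sum went from 38930 to 26880 CPM. Synaptogenic factors had 11 down and 1 up of 20, 12 and 2 adjusted over the list alone (−0.50, adjusted p = 0.000156, 0.311 with an estimated correlation), with the phagocytic receptor Mertk from 531 ± 144 to 244 ± 35.8 CPM (−1.39, adjusted p = 0.00158) and the matrix protein Tnc changed by −0.68. Of these calls, 0 of 19 homeostatic, 0 of 8 marker and 0 of 12 synaptogenic ones remained without WT replicate 1 (edgeR). Their log2 fold changes stayed near those with it, −0.98 for Aldh1l1 (adjusted p = 0.134), −1.23 for Grin2c (0.104), −1.32 for Mertk (0.102) and −0.70 for Tnc (0.143). At the preset correlation the homeostatic list passed with a median of −0.60 (camera, adjusted p = 2.2e-09) without WT replicate 1. At an unadjusted p under 0.05, 13 of 28, 6 of 10 and 6 of 20 genes passed without it. WT 1 and 4, low in endothelial markers, also held more astrocyte marker RNA (45770 and 43950 CPM) than WT 2 and 3 (33480 and 32530 CPM).

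With the endothelial level as a covariate, chosen after seeing the data, a part of these calls remained and the medians were smaller. That level mainly set WT 1 and 4 apart from the other libraries, so the change cannot be assigned to endothelial RNA. For interferon 3 of 26 remained (median 0.79), for MHC class I 6 of 12 (0.58), for cholesterol 15 of 21 (−0.70) and for glycolysis 1 of 9 (−0.22). For the pan-reactive list 2 of 6 remained (0.34), for the A1-labelled 4 of 7 (0.77) and for the A2-labelled 1 of 8 (1.02). For homeostatic astrocyte genes it was 4 of 19 (−0.36), for synaptogenic factors 2 of 12 (−0.21) and for astrocyte markers 4 of 8 (−0.39).

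The 10 largest falls held forebrain transcription factors and neighbouring genes whose counts may be uncertain. They were Rpe65, a retinoid isomerase, Ppp1r3g, a glycogen regulator (−2.17), the chemosensory chaperone Rtp1 (−2.11), the adhesion molecule Kirrel2 (−2.08), Gphn, gephyrin (−1.92), the receptor Gpr3 (−1.81), nephrin Nphs1 (−1.80), Nphs1os (−2.87), Fezf2 (−1.74) and Emx2 (−1.68). Kirrel2, Nphs1 and Nphs1os are neighbours on chromosome 7. Where such genes overlap, their reads cannot be told apart if the counting did not use strand, which is not given. Rpe65 (−2.22) remained called without WT replicate 1 (adjusted p = 0.0249). The calls of the others were lost, with log2 fold changes of −2.16 for Ppp1r3g (adjusted p = 0.0889), −3.07 for Rtp1 (0.204), −1.95 for Kirrel2 (0.102), −2.40 for Gphn (0.174), −1.74 for Gpr3 (0.15), −1.84 for Nphs1 (0.111), −2.63 for Nphs1os (0.106), −1.63 for Fezf2 (0.122) and −1.66 for Emx2 (0.0671). Gphn was also lost without APP replicate 1 (adjusted p = 0.0782), and Rtp1 without WT 2 (0.0562), WT 3 (0.0533), WT 4 (0.0552), APP 1 (0.176), APP 2 (0.0803) or APP 3 (0.0699). Ide, which degrades amyloid peptides, fell from 263 ± 27.6 to 98.5 ± 4.00 CPM (−1.49, SE 0.08, adjusted p = 9.62e-05; −1.46 and 0.0141 without WT replicate 1). Its neighbours Btaf1 (−0.37) and Fgfbp3 (−0.69) fell too and were lost without WT replicate 1. Amyloid processing did not pass as a list (adjusted p = 0.782, median 0.01 against a test pointing down).

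Several of the other lists moved with the libraries WT 1 and 4. Cell cycle genes rose in 6 of 25 cases, also 6 adjusted over the list alone (median 0.56, adjusted p = 0.00264, 0.327 with an estimated correlation, 0.0649 without WT replicate 1). Immediate early genes rose in 4 of 28, also 4 adjusted over the list alone (0.89, adjusted p = 0.000125, 0.435 with an estimated correlation, 0.0557 without WT replicate 1). Endothelial markers passed as a list (1.61, adjusted p = 0.00144, 0.435 with an estimated correlation, 0.0332 without WT replicate 1, 0.307 without WT 1 and 4). Of the 12 genes 0 were called by edgeR, 0 adjusted over the list alone, 3 by DESeq2 and 0 by limma voom. At an unadjusted p under 0.05 there were 3 with edgeR, 12 with DESeq2 and 12 with limma voom. Their estimated correlation was 0.988, so the 12 genes are not separate observations. Mural and fibroblast markers rose in 4 of 12, also 4 adjusted over the list alone (1.09, adjusted p = 0.000797, 0.381 with an estimated correlation, 0.0657 without WT 1 and 4). Of these calls 0 of 6 cell cycle, 0 of 4 immediate early and 0 of 4 mural ones remained without WT replicate 1 (edgeR), with 4 of 25, 4 of 28 and 2 of 12 genes at an unadjusted p under 0.05. The medians were then 0.25, 0.080 and 0.50, and without WT 1 and 4 they were 0.12, −0.13 and 0.030. Ependymal and choroid plexus markers rose in 7 of 10, 10 adjusted over the list alone (2.04, adjusted p = 3.66e-06, 0.188 with an estimated correlation, 5.96e-05 without WT 1 and 4, 4.42e-06 with the endothelial covariate), with the cilium regulator Foxj1 up by 2.15, and 0 of 7 remained called without WT replicate 1 (edgeR), where 6 of 10 had an unadjusted p under 0.05, the median was 0.91 and Foxj1 rose by 1.03. Oligodendrocyte markers rose in 1 of 12, also 1 adjusted over the list alone (2.52, adjusted p = 0.0435, 0.604 with an estimated correlation). Their adjusted p was 0.0871 without WT replicate 1 (median 1.02), 0.0851 without WT 3, 0.0525 without WT 4 and 0.0882 without APP 1. Neuron (adjusted p = 0.537), oligodendrocyte precursor (0.0652), border macrophage (0.361), erythroid (0.708) and sex-linked (0.599) lists did not pass, and markers of monocytes, neutrophils and lymphocytes were too low to test.

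The interaction asks which responses differ between the cell types. The disease-associated, lysosomal, cholesterol, lipid and glycolysis lists had the higher fold change in microglia, the lysosomal one not with an estimated correlation. In astrocytes the fall of cholesterol and glycolysis genes was not called with an estimated correlation either (adjusted p = 0.0885 and 0.327), and lysosomal and lipid lists did not pass. In turn, microglial identity genes went down in microglia (0.235 for the homeostatic list and 0.426 for the markers with an estimated correlation) and up in the astrocyte libraries. Interferon response (adjusted p = 0.0745), MHC class I (0.925, median −0.07 against a test pointing up), cytokine (0.273), pan-reactive (0.837, median 0.10 against a test pointing down), A2-labelled (0.171) and homeostatic astrocyte (0.171) lists did not differ past the threshold.

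Of 14802 genes tested, 3357 differed (edgeR), 1905 with the higher fold change in microglia and 1452 with the lower. Without the mouse WT replicate 1, 868 did. The share with the higher fold change, 56.75%, was 47.63% with DESeq2 size factors and 45.91% without WT replicate 2. Cholesterol biosynthesis differed in 23 of 24 genes, all higher in microglia (median 1.58, camera, adjusted p = 1.09e-22, 0.0222 with an estimated correlation). Disease-associated genes had 23 higher and 8 lower of 40 (1.52, adjusted p = 2.58e-22, 0.00393 with an estimated correlation), lysosome 24 and 2 of 34 (0.86, adjusted p = 2.3e-16, 0.0892 with an estimated correlation), lipid handling 11 and 6 of 27 (0.61, adjusted p = 3.87e-07, 0.00393 with an estimated correlation), and glycolysis 12 and 1 of 19 (1.39, adjusted p = 2.3e-16, 0.0222 with an estimated correlation). The disease-associated astrocyte list had 7 and 2 of 26 (0.61, adjusted p = 0.00177, 0.399 with an estimated correlation). Homeostatic microglia had 2 higher and 23 lower of 30 (−1.81, adjusted p = 8.51e-24, 0.00393 with an estimated correlation), microglial markers 0 and 8 of 10 (−2.62, adjusted p = 4.68e-19, 0.00393 with an estimated correlation), and complement 2 and 10 of 27 (−0.62, adjusted p = 2.92e-05, 0.0443 with an estimated correlation). MHC class II had 0 and 6 of 13 (−2.16, adjusted p = 0.000134, 0.202 with an estimated correlation), border macrophages 1 and 5 of 12 (−1.57, adjusted p = 0.00494, 0.191 with an estimated correlation), and the A1-labelled list 1 and 3 of 13 (−0.69, adjusted p = 0.0351, 0.542 with an estimated correlation). The astrocyte side of these microglial lists holds the microglial share given above. None of these list differences was tested with libraries left out.

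Gpnmb (8.88, adjusted p = 1.30e-07, edgeR), Dkk2 (8.01), Mamdc2 (7.34) and Baiap2l2 (7.26) had the largest differences toward microglia. Fabp5 differed by 6.25 (adjusted p = 3.42e-08), with 5.35 in microglia and −0.83 in astrocytes, the latter −0.79 without WT replicate 1 (adjusted p = 0.216), and the synaptic adhesion gene Lrrtm3 by 6.00. Toward astrocytes lay genes of myeloid cells with few astrocyte counts in WT, and Kcnq1, with few counts in microglia. Susd3 differed by −4.65 (adjusted p = 4.22e-05). The chemokine receptor Ccr1 went from 0 to 9 counts over the astrocyte groups. Against the floor of 3 counts it was 1.95-fold higher in APP, with a 95% counting lower limit of 1.28. Its difference between the cell types had an adjusted p of 0.168 (edgeR) without APP replicate 1. Ccr2 went from 1 to 25 (ratio 16.2, 95% counting interval 2.66 to 667; adjusted p = 0.0515 without WT replicate 1 and 0.165 without APP replicate 1). Bcl2a1b, a survival gene with near-identical copies, went from 0 to 85. Against the floor it was 18.4-fold higher, with a 95% counting lower limit of 14.6 (adjusted p = 0.0708 without APP replicate 1, edgeR). The lectin gene Clec4a2 went from 1 to 14 (ratio 9.09, interval 1.38 to 384; adjusted p = 0.076 without WT replicate 1 and 0.051 without APP replicate 1). The channel gene Kcnq1 had 5 and 3 counts over the microglia groups (ratio 0.351, interval 0.0544 to 1.8), and its difference had an adjusted p of 0.451 without WT replicate 1. The response of C3 did not differ between cell types (0.73, adjusted p = 0.577), but did without WT replicate 1 (2.20, adjusted p = 0.0459), and was −1.09 without APP replicate 1 (adjusted p = 0.319). That of App did not differ either (−0.66, adjusted p = 0.398).

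The calls of the cell types were compared over 12598 genes tested in both. Genes up in both numbered 520, where 261 were expected if the calls were independent (odds ratio 3.03, Fisher's exact test, p = 5.96e-68). The odds ratio was 15.6 without WT replicate 1, from at most 28 astrocyte rises, mostly transcripts typical of microglia. It is therefore no measure of a stronger shared response. Genes down in both numbered 385 against 356 expected (odds ratio 1.12, Fisher's exact test, p = 0.0641). That p was 0.0331 without WT replicate 1 (odds ratio 11.8, from at most 6 astrocyte falls), 0.0258 without WT 2 and 0.032 without APP 4. The odds ratio was 0.938 without APP 1. Opposite calls were fewer than expected, 236 against 353 for genes up in microglia and down in astrocytes and 195 against 263 for the reverse. Across genes the fold changes correlated at Pearson r = 0.288 and Spearman rho = 0.220, where genes are not independent replicates and the cell types come from the same mice. Of the 1812 rises in astrocytes, the microglial share gave at least 0.5 of the rise in 147 (8.11%), among them the 10 largest, and under 0.1 in 1490 (82.2%). Genes that set the share can be among the 147.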

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

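All tests in this part were chosen after the results were seen, except the counts of other splits of the samples and the tests of the difference between the cell types.

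Chance was tested by splitting the mice otherwise into groups of 4 and 5. In microglia 1 of 100 splits, the real one, called as many as 5022 genes, and the highest other split called 0. In astrocytes 1 of 100 splits, the real one, called 3836 genes, and the highest other called 58. For the difference between cell types 1 of 100 splits, the real one, called 3357 genes, and the highest other called 91. At 1 of 100 splits, a chance split of the samples is unlikely for each of the 3 counts. The other splits mix WT and APP mice, which raises the spread within their groups. This test does not address the difference of WT 1 and 4 from the other libraries.

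The fold changes of APP against WT differed between the cell types in 12 lists, as medians of microglia minus astrocytes on the log2 scale. Whether these differences hold with libraries left out was not tested. Cholesterol biosynthesis (1.58), disease-associated microglia (1.52), glycolysis (1.39), lysosome (0.86), lipid handling (0.61) and disease-associated astrocyte genes (0.61) lay higher in microglia. Microglial markers (−2.62), MHC class II (−2.16), homeostatic microglia (−1.81), border macrophages (−1.57), A1-labelled genes (−0.69) and complement (−0.62) lay lower. For the first 3 of these the microglial share gave medians of 1.2, 1.03 and 0.855 of the astrocyte rises. Their differences are therefore no measure of a response of astrocytes. With an estimated correlation 7 of the lists were called, and lysosome (adjusted p = 0.0892), disease-associated astrocyte genes (0.399), MHC class II (0.202), border macrophages (0.191) and A1-labelled genes (0.542) were not.

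Single genes differed too. The largest differences toward microglia were those of Gpnmb (8.88), Dkk2 (8.01), Mamdc2 (7.34), Baiap2l2 (7.26), Fabp5 (6.25) and Lrrtm3 (6.00), and toward astrocytes those of Ccr1 (−5.46), Ccr2 (−5.40), Kcnq1 (−4.86), Bcl2a1b (−4.67), Susd3 (−4.65) and Clec4a2 (−4.50). Fitted values of the latter genes rest on few counts in WT astrocytes or, for Kcnq1, in microglia. Ccr1 and Bcl2a1b had 0 counts in WT astrocytes, so their values and their place among the largest are no estimates of size. Of 25 genes named in both cell types, Cst7 (2.56), H2-K1 (0.95) and Ide (0.87) had the higher log2 fold change in microglia, and Clec7a (−3.99), Itgax (−3.04), H2-Aa (−2.55), Cd74 (−2.18) and Cd14 (−1.17) in astrocytes. Clec7a and Itgax had 1 count each in WT astrocytes. The microglial share gave 1.45 of the astrocyte rise of Cd14. It gave a median of 1.18 of the astrocyte rise of the disease-associated list and 1.03 of that of MHC class II.

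Of 366 groups of 4 or 5 libraries tested, 28 held a library far from the others. Where the reads of a gene lay in a single library of a group, that library stands apart by construction, so for such groups the limits have no chance level. This holds for Asb11 in WT microglia and Ccl4, Clec7a and Itgax in WT astrocytes. In microglia WT replicate 1 stood apart in Apbb2 (87.7 CPM) and Igf1 (16.5 CPM), WT 3 in Asb11 (0.216 CPM) and Dkk2 (0.324 CPM), and WT 4 in Ggta1 (164 CPM) and Mrc1 (282 CPM). APP 1, the male, stood apart in the class II genes Cd74 (2170 CPM) and H2-Aa (584 CPM). APP 3 did in Egr2 (123 CPM), APP 4 in Mbp (225 CPM) and Mrc1 (40.7 CPM), and APP 5 in Aplp2 (765 CPM), Cspg4 (179 CPM), the sum of oligodendrocyte precursor markers (185 CPM) and the share of Rn45s (6.46%).

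In astrocytes WT 1 stood apart in Nphs1os (5.51 CPM), WT 2 in Ccl4 (0.1003 CPM), Cd74 (1.56 CPM) and Clec7a (0.0502 CPM), and WT 3 in Itgax (0.0437 CPM). APP 1 did in Iigp1 (35.4 CPM), which is interferon-induced. APP 3 did in C3 (88.4 CPM) and Cd68 (10.1 CPM), APP 4 in App (980.4 CPM), Emx2 (23.5 CPM) and the sum of oligodendrocyte markers (4500 CPM), and APP 5 in Cd44 (36.7 CPM) and Vwf (138 CPM).

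Transcripts specific to microglia lay higher in the APP astrocyte libraries. With 1 share per library estimated on one set of genes, the difference of the genes kept aside was within 2-fold of the predicted one in 81 of 92 genes, a share of 0.88. Microglial RNA or cells in these libraries are therefore a candidate explanation for them. The genes kept aside had also been chosen for at most 3% of the microglial level in astrocytes. The result thus holds for such genes only and is in part brought about by that choice. The same share gave a median of 0.00187 of the rise of the pan-reactive astrocyte genes and 0.0068 of the difference of C3. This argues against microglial RNA as their source and does not address RNA of other cell types. With the endothelial level as a covariate the C3 difference was 1.79, against 2.21 without it, and the pan-reactive median was smaller, as given above. The astrocyte share in microglia libraries was 2.54% ± 1.62 in WT and 2.79% ± 1.47 in APP, with 0.980% and 1.41% in WT 1 and 4 and 4.42% and 3.35% in WT 2 and 3. Why the share was higher in APP stays open: more microglia in these brains, closer contact of the cells or the sort itself were not tested.

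WT astrocyte replicates 1 and 4 lay apart from the other astrocyte libraries, and the microglia libraries of the same mice differed from WT 2 and 3 as well. A lower share of all other cell types in them cannot be told apart from the pattern. The log2 ratios of the marker sums to WT 2 and 3 were −2.59 for endothelium and −1.97 for ependyma, which differ by 0.62. Other marker sums fell less or not at all, with log2 ratios of −0.98 for mural cells, −0.13 for oligodendrocytes and 0.10 for microglia. A like factor over all marker sums was thus not seen. A base level of such markers in astrocytes could hide a small share, which was not tested. The microglial share was 0.168% and 0.236% in WT 1 and 4 against 0.385% and 0.355% in WT 2 and 3. Depth and the share of Rn45s stay open too, since for each of them 1 of the 2 libraries lay within the range of the other 7. A loss of endothelial and ependymal cells, alone or with other types, may be a candidate explanation. The 382 genes called with the endothelial level as a covariate cannot decide this. That level mainly sets WT 1 and 4 apart, so any other trait of these 2 libraries could remove calls in the same way. Leaving both out gave 142. Whether the sex of WT 1 plays a part was not tested, since WT 4 is male and WT 1 is the only WT female.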

How the results depend on the processing

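Leaving out WT replicates 1 and 4 together, the endothelial level as a covariate, the interaction's filter by cell type and genotype and the overlap with a mouse left out were chosen after the results were seen, and the other alternatives before the data were examined.

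Direction and side of the threshold held under every alternative for 88 of 112 named genes in microglia, 0 of 108 in astrocytes and 7 of 14 in the interaction. In astrocytes males alone left a lone APP library and carried no call, so no called gene could hold there. Without WT replicate 1, 28 of the 108 named astrocyte genes kept direction and side. These include genes called in neither fit, such as C3 and App. The called ones among them were transcripts typical of microglia, such as C1qa and Trem2, except for Ide and Rpe65. Among the lists called, they held for 2 of 17 in microglia and 4 of 22 in astrocytes, mostly because an estimated correlation removed the others. With that correlation 2 lists in microglia and 4 in astrocytes were called. With fry, direction and side held for all 17 lists in microglia and 19 of 22 in astrocytes.

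In microglia 5022 genes were called. Males alone, with fewer samples, gave 2112, a 2-fold threshold 1423, and leaving out WT 1 and 4 gave 2330. Leaving out 1 library gave 2641 to 5085. The other alternatives lay within 1.5 times. In astrocytes 3836 genes were called. Quality weights gave 2113, males alone 0 (edgeR, 1575 at an unadjusted p under 0.05), a 2-fold threshold 1230, leaving out WT 1 and 4 142, and the endothelial covariate 382. Leaving out 1 library gave 34, without WT 1, to 4217. DESeq2 gave 5105 and limma voom 3798. For the interaction, with 3357 genes, leaving out WT 1 and 4 gave 937 and leaving out 1 mouse 868 to 3346. Without WT 1 no WT female is left, so with a sex covariate the genotype contrast compares the 3 WT males with the lone APP male. The loss in astrocytes is in part brought about by that, and its cause was not tested further.

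The replicate number is only a number between WT and APP: profiles of the same number correlated at r of −0.313 to 0.0252 in microglia and −0.345 to 0.049 in astrocytes, and 0 of 4 matched their own number best. As a replicate block it gave 1907 genes in astrocytes and C3 an adjusted p of 0.013 there.

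No gene that was both named and called reversed. Of the 5022 calls in microglia, 5019 kept their direction without WT 1 and 4, 5021 in females, 5020 without the sex covariate and 5017 of 5018 tested in males. Alas2 in microglia (−0.06) was 0.094 with limma voom, 0.73 in females, 0.13 with the replicate block, 0.11 with the deposited values and −0.74 to 0.73 with 1 library left out. Alas2 in astrocytes (0.71) was −0.052 without the sex covariate, −0.42 in males, −0.86 without WT 1 and 4, −0.57 with the endothelial covariate and −0.43 to 2.02 with 1 library left out. Slc4a1 in astrocytes (1.11) was −0.81, −1.25 and −0.040 in males, without WT 1 and 4 and with the covariate, and −0.85 to 3.24 with 1 library left out. Stmn2 in astrocytes (1.09) was −0.026 without WT 1 and 4 and −0.13 with the covariate. Immediate early genes in astrocytes had an adjusted p of 0.751 without WT 1 and 4 and endothelial markers 0.901 with their own level as covariate, both with the direction reversed. The C3 difference between cell types ranged from −1.09 without APP 1 to 2.20 without WT 1, and that of App was 0.060 without WT 1 and 4. The odds ratio for shared falls was 0.994 without the sex covariate and 0.938 to 11.8 with 1 mouse left out. The value of 11.8 came from at most 6 falls in astrocytes. The cause was not tested.

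Depth limits genes with few counts in a group, such as Ccr1 and Bcl2a1b in WT astrocytes, for which only a lower bound of the fold can be given.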

Other observations

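The tests in this part were chosen after the results were seen.

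Lists chosen after seeing the data gave further values, and no test of them is given. Ribosomal protein genes rose in 76 and fell in 1 of 81 in microglia (median 1.16), and still in 74 of 81 without WT 1 and 4 (median 0.94). In the same libraries Malat1 took 2.71% to 2.96% of counts in WT and 1.36% to 1.97% in APP, and Rn45s 5.74% to 9.76% and 3.20% to 6.46%, so a wider shift in RNA composition was not set apart from this rise. In astrocytes 55 of 80 rose (median 0.52), but 0 of 81 without WT 1 and 4 (edgeR). Clock and glucocorticoid-responsive genes fell in 12 and rose in 1 of 15 in astrocytes (median −0.68), among them the clock output gene Dbp (−1.16) and its regulators Per1 (−0.96) and Nr1d1 (−0.95), but 0 of 15 were called without WT 1 and 4 (edgeR), where the median was −0.46. In microglia 8 fell and 3 rose of 15 (median −0.77). The labels give no time of day.

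Transcription factors of the forebrain fell in 8 of 10 cases in astrocytes (median −1.39), and in 5 of 11 without WT 1 and 4 (median −1.20). The list was written after Fezf2 and Emx2 were seen among the largest falls and holds both. Lhx2 fell by 1.39 on the log2 scale, Otx1 by 1.38 and Nr2e1 by 1.18. Those of hindbrain and diencephalon had 4 up and 1 down of 11 (median 0.63), among them Zic4 (1.09), Zic1 (0.69) and Irx3 (0.65), and 0 of 11 were called without WT 1 and 4 (edgeR, median 0.31).

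A stretch of neighbouring genes on chromosome 19, from Fgfbp3 (start 36917550) to Ide (end 37334544), was lower in APP mice. Ide changed by −0.66 in microglia and −1.49 in astrocytes, Btaf1 by −0.61 and −0.37, Fgfbp3 by −1.10 and −0.69, and Cpeb3 by −0.09 and −0.76, while Tnks2 before the stretch did not change (−0.00 and −0.02) and Kif11 after it rose (1.53 and 1.63), in astrocytes by 1.07 without WT replicate 1 (adjusted p = 0.168). A mean as low in both cell types was found in 3 of 11947 stretches of 4 neighbouring genes, a share of 0.00025, which tests nothing, since the stretch was picked for its low values. Cpeb3 was not called in microglia (adjusted p = 0.721), and Fgfbp3 in microglia lost its call under 17 of 21 alternatives. A difference in sequence or copy number between the WT and APP animals, which may come with the strain in which a knock-in was made, therefore cannot be told apart from a response of these genes, since counts per gene hold no sequence. Astrocyte RNA in the microglia libraries would give 0.0909 of the fall of Ide there, which argues against astrocyte RNA as its cause.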
